A study of Homo sapiens with 18 samples.

How the data were processed

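RNA from HEK293T cells, a human embryonic kidney line that is easily transfected, was sequenced after the cells had received RNA base editors. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was enriched with magnetic beads, and strand-specific libraries were made with a NEBNext directional kit. Per the submitters' processing notes, cutadapt and STAR 2.6.1b were used and the genome build was hg19 (GRCh37). The caller of edited sites and its filters are not given in the sources used here.

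The series has 18 samples, of which 16 have a list of sites that was analysed here. The 2 non-treated samples had no list that could be used here, so no background from untreated cells is given. Each list deposited by the authors holds, per the file headers, a chromosome, a position and an A-to-G rate as a fraction of 1. The fractions were multiplied by 100 and are called levels, in percent. The lists hold no read counts, strand or gene, so the depth behind each level is unknown and no interval that needs depth was computed. The lowest level listed was 5.50%, and a position absent from a list lay outside the authors' limits, which is not a level of 0. No position occurred more than once in a library. Over sites shared by 2 libraries of an editor, at most 3.38% had equal levels, so no library was a copy of another.

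Groups came from the labels, as 4 editors, 2 guide conditions and 2 replicates of each combination. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The guide conditions of an editor were joined to 4 libraries for comparisons between editors, the smallest grouping whose exact test can pass 0.05. This treats the libraries of both guides as exchangeable. Exact permutation within guide conditions gives a p of at least 0.0556, so no pair could be called that way. Site counts on the log2 scale and per-library median levels were compared by exact permutation tests, two-sided on the absolute difference, over 70 assignments of 4 against 4 libraries, for which the smallest possible p is 0.0286. Benjamini-Hochberg adjustment was over the 6 pairs of editors. Guide conditions were compared by exact permutation of the guide labels within editors, over 1296 assignments. The Jaccard index (shared sites divided by the union) was compared between replicate pairs and pairs of different guides by a one-sided exact permutation over 81 arrangements. Listing of single positions was compared by Fisher's exact test, two-sided, over 8 EZH2 and 8 NT libraries. A site was called recurrent for an editor when at least 2 of its 4 libraries listed it.

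Levels of sites listed in all 4 libraries of an editor were compared between guides with limma 3.58.1 on the logit scale, with levels held 0.5 percent away from 0 and 100, for editors with at least 30 such sites. The share of sites per region of DECOR and REPAIRv1 was compared with limma on log2 of 100 times (sites + 0.5) divided by (library total + 1), for regions with at least 8 sites summed over the 8 libraries. Calls used a Benjamini-Hochberg adjusted p under 0.05. On simulated data, the test of 345 DECOR sites recovered 96.5% of shifts of 2 on the log2 odds scale and 0% of shifts of 1. That of 38 hfDECOR-V106G sites recovered 66.7% of shifts of 2, and that of 2426 REPAIRv1 sites recovered 80.5%. In these simulations all sites of an editor had the same spread, and 86, 9 and 200 sites were shifted. Real sites may differ in spread and fewer may change, so recovery on the real lists may be lower. The test of 1564 regions, 200 of them changed, recovered 0%, 20.0% and 69.5% of log2 shifts of 1, 2 and 3, with 0, 3 and 15 false calls. The slope of fitted on true shifts was 0.759, 0.797 and 0.778, so its log2 differences came out too small.

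The annotation at hand, GENCODE 29, is on GRCh38, another build than that of the lists. When positions were read as if they were on GRCh38, 10.0% fell into exons of coding genes, against 3.42% to 5.22% after shifts of 1000000 or 3000000 bases, so coordinates were neither mixed nor converted. No genome sequence of GRCh37 was used. The planned tests of sequence context, of genomic features, of genes and of gene lists were therefore not run, and 100 kb regions in fixed windows took the place of genes. Positions are given as in the lists, whose headers do not name the coordinate convention.

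A rule fixed before the data were examined sets how many genes and sites are named and how they are ranked, with positions in place of genes where the lists give none. The regions of 100 kb that took the place of genes were chosen after the data were seen. The text names the EZH2 target, up to 10 regions per direction with the largest log2 difference among those called, the 8 regions per editor with the most sites listed in both replicates of a guide condition, the 5 sites per editor with the highest mean level among sites in all 4 libraries, sites recurrent in all 4 editors, and up to 3 guide-dependent sites per direction. The longer of these lists are summarised with examples. Alternatives were level minimums of 20% and 50%, sites in both replicates, each library left out in turn, other measures of overlap, other pseudocounts, filters and windows, and replicate numbers as a block. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.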

Results

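The A-to-G sites of HEK293T cells carrying RNA base editors were compared between 4 editors. DECOR joins an RNA-guided Cas13 protein to an evolved bacterial adenosine deaminase, and hfDECOR-F148A and hfDECOR-V106G are versions of it named after amino acid changes. REPAIRv1 joins a Cas13 protein to the deaminase domain of a human ADAR enzyme. Adenosine deaminases turn adenosine into inosine, which is read as G in sequencing. Each editor was combined with a guide labelled EZH2 or one labelled NT, known from the study as non-targeting. There were 2 libraries per combination, 16 in all. The lists held 43935 entries at 23392 distinct positions on 23 chromosomes, with levels between 5.50% and 100%. Read depth is unknown, so a longer list can reflect deeper reading as well as more editing.

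The first comparison asks how many transcriptome positions each editor altered. REPAIRv1 libraries listed the most sites, 7556.75 ± 326 (SD, n = 4), and DECOR libraries 2722.5 ± 148.3. The hfDECOR libraries listed far fewer, with 457 ± 83.8 sites for hfDECOR-V106G and 247.5 ± 9.88 for hfDECOR-F148A. The geometric mean count was 2.78-fold higher for REPAIRv1 than for DECOR, 6.03-fold higher for DECOR than for hfDECOR-V106G and 10.99-fold higher for DECOR than for hfDECOR-F148A. REPAIRv1 exceeded hfDECOR-V106G 16.7-fold and hfDECOR-F148A 30.5-fold, and hfDECOR-V106G exceeded hfDECOR-F148A 1.82-fold. In all 6 pairs every library of one editor lay above every library of the other. The exact permutation p was 0.0286 in each pair, adjusted p = 0.0286, the smallest that 4 against 4 libraries can give. Among sites at 20% or more, the fold of REPAIRv1 over DECOR rose to 4.45, over hfDECOR-V106G to 32.8 and over hfDECOR-F148A to 65.9. With sites required in both replicates, these folds were 4.66, 36.8 and 78.4, and that of DECOR over hfDECOR-F148A was 16.8. Among sites at 50% or more, REPAIRv1 exceeded DECOR 24.0-fold and hfDECOR-F148A 376-fold, on few hfDECOR-F148A sites.

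**Figure D1:**
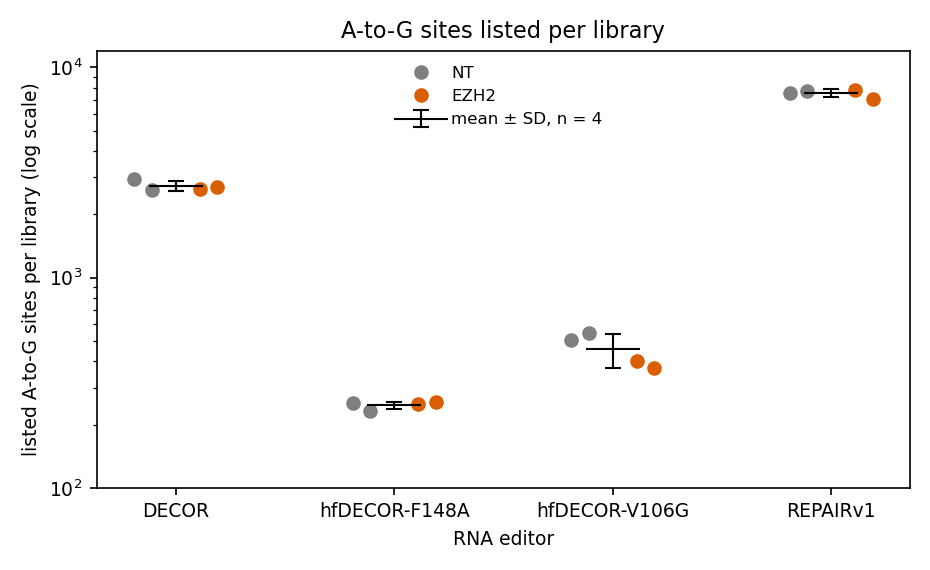
Listed A-to-G sites per library (log axis) for the 4 editors. Points are libraries, coloured by guide, and the bars give mean ± SD (n = 4). The 4 editors do not overlap, from 233 to 255 sites for hfDECOR-F148A up to 7109 to 7843 for REPAIRv1.

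Sites were also listed at higher levels for REPAIRv1. The median level per library was 27.8% ± 0.410 (SD, n = 4) for REPAIRv1, 19.5% ± 0.397 for DECOR, 17.7% ± 0.544 for hfDECOR-V106G and 16.7% ± 0.378 for hfDECOR-F148A. Of the REPAIRv1 sites, 78.7% ± 0.750 were at 20% or more, against 49.1% ± 1.43 for DECOR, 40.2% ± 2.55 for hfDECOR-V106G and 36.5% ± 1.22 for hfDECOR-F148A. Levels of 50% or more were seen at 590.25 ± 60.2 sites per REPAIRv1 library, 24.5 ± 1 per DECOR library, 1.75 ± 0.957 per hfDECOR-F148A library and 0.75 ± 0.5 per hfDECOR-V106G library. Median levels differed by 8.35 percentage points between REPAIRv1 and DECOR, 1.72 between DECOR and hfDECOR-V106G, 2.80 between DECOR and hfDECOR-F148A and 1.08 between the hfDECOR versions. Each of the 6 pairs had an exact permutation p of 0.0286, adjusted p = 0.0286. The call between the hfDECOR versions was lost when any of 5 of the 8 libraries was left out, that between DECOR and hfDECOR-V106G without DECOR-EZH2 replicate 1 (adjusted exact permutation p = 0.0571 each), and all 6 calls were lost among sites at 20% or more and among sites in both replicates. In the 3 pairs with REPAIRv1 the differences there were 5.23 to 6.13 points and 9.49 to 11.7 points. Their exact permutation p stayed at 0.0286, and the adjusted p rose to 0.0571 because the other 3 pairs no longer reached the smallest p. Of those, DECOR minus hfDECOR-F148A was -0.300 points and hfDECOR-V106G minus hfDECOR-F148A -0.900 points at 20% or more. Restricted to sites listed by both editors of a pair, REPAIRv1 stayed above DECOR by 5.67 points and above hfDECOR-V106G by 7.06 points, and DECOR above hfDECOR-F148A by 4.58 points and above hfDECOR-V106G by 3.67 points, adjusted exact permutation p = 0.0429 each. On such sites REPAIRv1 minus hfDECOR-F148A was -2.30 points (SE 11.8, adjusted exact permutation p = 1), on 11 sites of which each hfDECOR-F148A library listed 1 to 7, and hfDECOR-V106G minus hfDECOR-F148A 0.863 points (adjusted p = 0.137, exact permutation). Each library's median here covers only the sites it listed. For REPAIRv1 and DECOR these were 117 to 136 and 74 to 89 of 215 sites, so the same sites were not compared. Site by site, over the 52 sites recurrent in both, the median difference of REPAIRv1 minus DECOR was 2.94 points, with REPAIRv1 higher at 40.

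**Figure D2:**
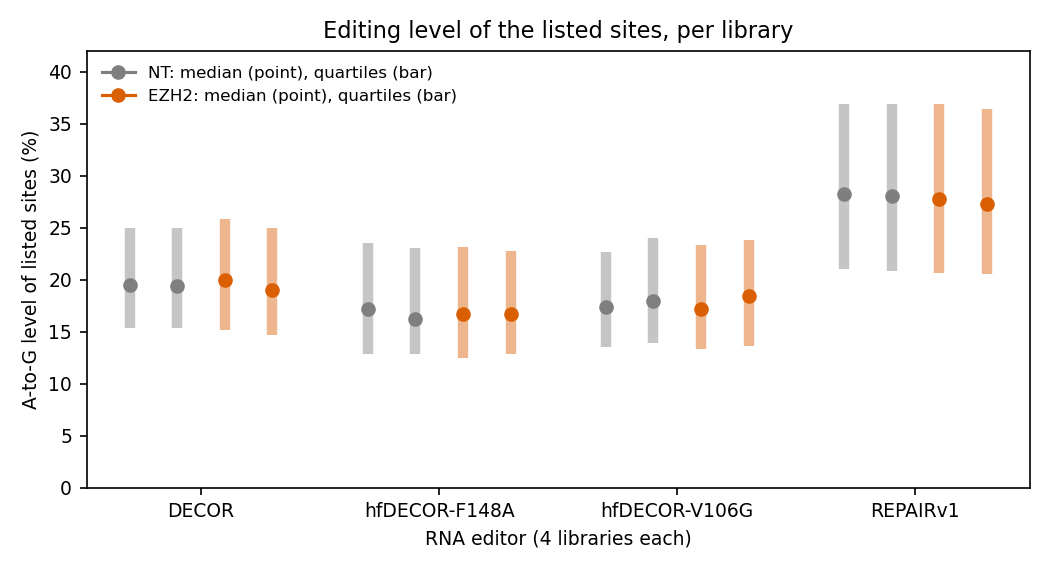
Level of the listed sites in each library, in percent, with the median as a point and the quartiles as a bar, coloured by guide. Medians lie between 27.3% and 28.2% for REPAIRv1 and between 16.2% and 20% for the other editors.

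The EZH2 guide is named for the transcript of EZH2, the catalytic subunit of the Polycomb repressive complex that methylates histone H3. A single position, 148515165 on chromosome 7 (GRCh37), was listed in all 8 EZH2 libraries and in 0 of the 8 NT libraries (Fisher's exact test, two-sided, p = 0.000155, adjusted p = 0.0137 over the 88 sites listed in at least 8 libraries). It was found from the lists themselves, as the only position with this full split among 23392. Its unadjusted Fisher p is therefore the smallest possible by selection, and the adjusted p covers only the 88 sites. EZH2 lies on chromosome 7 in GENCODE 29 (GRCh38), its GRCh37 span was not used here, and the position's exon or codon was therefore not assigned. Of the other positions, none differed by more than 4 libraries between the guides. The level was 53.0% ± 4.24 (SD, n = 2) for REPAIRv1, 46.7% ± 4.71 for DECOR, 44.6% ± 5.62 for hfDECOR-F148A and 33.9% ± 12.6 for hfDECOR-V106G. No pair of editors could be separated at this position, since 2 against 2 libraries give an exact permutation p of at least 0.333. For hfDECOR-V106G the replicates were 42.9% and 25%.

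Further sites were listed beside the target in 6 of the 8 EZH2 libraries. Within 200 bases and without the target itself, the DECOR libraries listed 3 and 5 sites, the hfDECOR-F148A libraries 1 and 0, the hfDECOR-V106G libraries 2 and 1, and the REPAIRv1 libraries 0 and 1. The NT libraries listed 0, against a mean of 1.62 per EZH2 library. The window was placed after these sites had been seen, so no p-value is given. With the target, the 9 positions ran from 148515062 to 148515165. DECOR sites spanned 104 bases, hfDECOR-V106G sites 35, hfDECOR-F148A sites 34 and REPAIRv1 sites 3. Position 148515131 was listed in both hfDECOR-V106G libraries at 53.6% and 30.2%, in each above the target's own level, and in both DECOR libraries at 26.7% and 32.1%. Position 148515132 was listed at 22.2% in a DECOR library, 23.3% in an hfDECOR-F148A library and 21.4% in an hfDECOR-V106G library. The target's rank by level was 2 of 250 and 4 of 255 sites in the hfDECOR-F148A libraries, 12 of 2641 and 53 of 2692 in the DECOR libraries, 5 of 400 and 73 of 373 in the hfDECOR-V106G libraries, and 438 of 7843 and 186 of 7109 in the REPAIRv1 libraries.

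**Figure D3:**
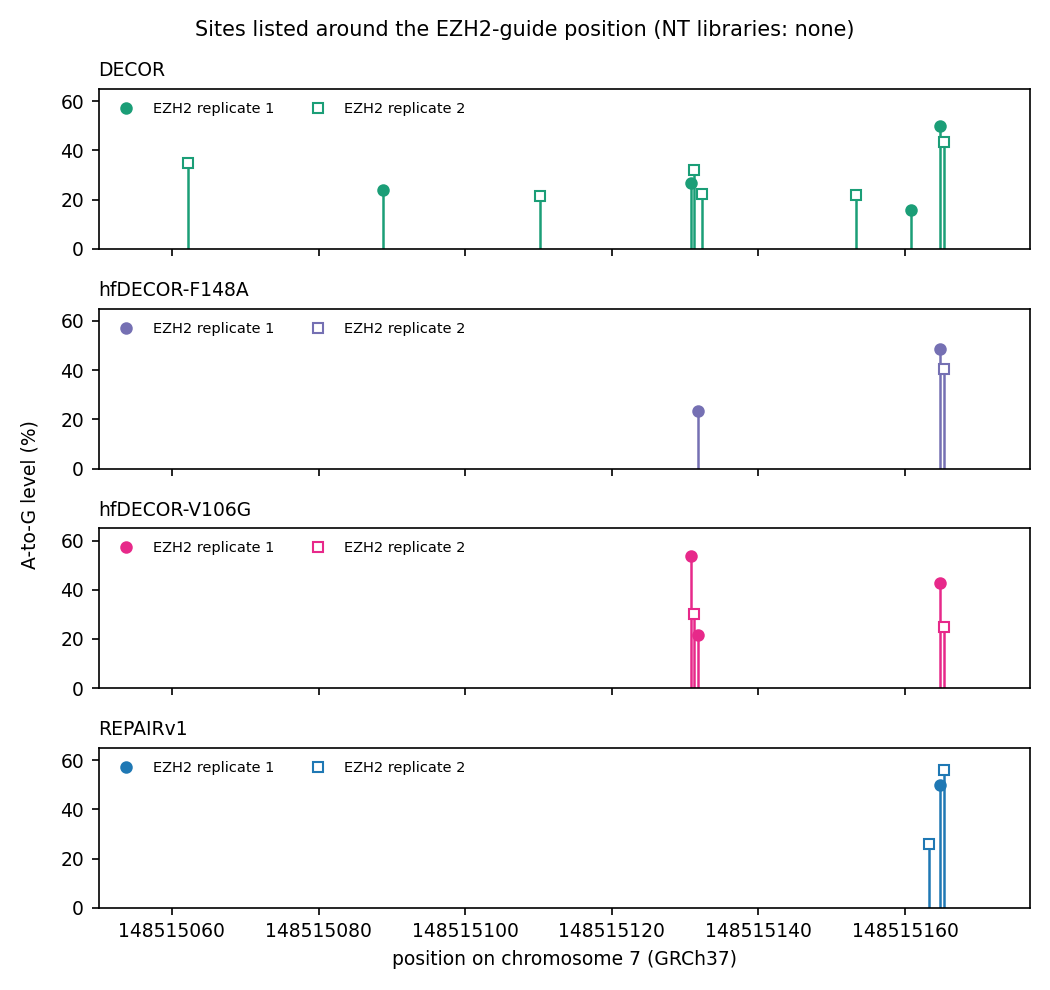
Level (percent) of every listed site around position 148515165 of chromosome 7 (GRCh37) in the EZH2 libraries, one panel per editor. Filled circles are replicate 1 and open squares replicate 2, drawn slightly left and right of the position. DECOR has 7 positions besides the target, hfDECOR-V106G 2, and hfDECOR-F148A and REPAIRv1 have 1 each.

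Over the 4 editors together, no difference between the guides in the length of the lists or in their levels passed the test. EZH2 libraries listed 0.920 times as many sites as NT libraries over the 4 editors (exact permutation within editors, two-sided, p = 0.145). The median level differed by -0.0850 percentage points, EZH2 minus NT (exact permutation p = 0.715). hfDECOR-V106G had the widest gap, with 527.5 ± 28.99 sites (SD, n = 2) with NT and 386.5 ± 19.1 with EZH2, a 1.36-fold difference. On the log2 scale the change with EZH2 was -0.45 (SE 0.08), larger than the spread between replicates, and the exact permutation p of 0.333 is the smallest that 2 against 2 libraries can give. Set against the mean guide effect of the other editors, it had an exact permutation p of 0.190, adjusted p = 0.506 over 8 such tests. DECOR had 2778.5 ± 228 with NT and 2666.5 ± 36.1 with EZH2, hfDECOR-F148A had 242.5 ± 13.4 and 252.5 ± 3.54, and REPAIRv1 had 7637.5 ± 155 and 7476 ± 519. Among sites listed in all 4 libraries of an editor, limma called 0 of 345 DECOR sites, 0 of 38 hfDECOR-V106G sites and 0 of 2426 REPAIRv1 sites between the guides, with 22, 1 and 128 sites at an unadjusted p under 0.05. hfDECOR-F148A had 15 such sites, too few for a fit. A site listed with one guide and missing with the other, such as the target, could not enter this test.

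Replicates with the same guide shared slightly more sites than libraries with different guides. The Jaccard index was 0.277 percentage points higher for the same guide (one-sided exact permutation p = 0.0247). Without the sites within 200 bases of the target, an alternative chosen after seeing the data, the difference was 0.199 points (exact permutation p = 0.148). As a share of the shorter list it was -0.260 points (p = 0.617, exact permutation), and among sites at 20% or more the Jaccard difference was 0.858 points (p = 0.0123, exact permutation). The call or its direction was also lost when any of 9 of the 16 libraries was left out.

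The editors' lists were then compared with each other. Libraries of one editor shared most sites for REPAIRv1, with a mean Jaccard index of 36.2% over 6 pairs, against 18.7% for DECOR, 13.4% for hfDECOR-V106G and 11.5% for hfDECOR-F148A. Between DECOR and REPAIRv1 libraries the mean index was 0.489%, where the unequal length of the lists limits its value. Recurrent sites numbered 7737 for REPAIRv1, 2238 for DECOR, 329 for hfDECOR-V106G and 157 for hfDECOR-F148A. DECOR and REPAIRv1 had 52 recurrent sites in common, 2.32% of the DECOR set. By contrast, 248 of the hfDECOR-V106G sites (75.4%) and 116 of the hfDECOR-F148A sites (73.9%) were recurrent with DECOR. The hfDECOR versions shared 69 sites, 43.9% of the smaller set. REPAIRv1 shared 5 sites with hfDECOR-V106G (1.52% of the smaller set) and 2 with hfDECOR-F148A (1.27%). These shares depend on single libraries: the first was 0.912% without REPAIRv1-EZH2 replicate 1, and the second was 0% without either hfDECOR-F148A-EZH2 replicate, 0.637% without any 1 REPAIRv1 library and 1.98% without hfDECOR-F148A-NT replicate 1. A single site was recurrent in all 4 editors, the EZH2 target on chromosome 7. At the shared sites, the level was lower in the hfDECOR libraries than in DECOR at 206 of 248 sites for hfDECOR-V106G and at 95 of 116 for hfDECOR-F148A, with median ratios of 0.783 and 0.761. No p-value was computed for these counts of shared sites.

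**Figure D4:**
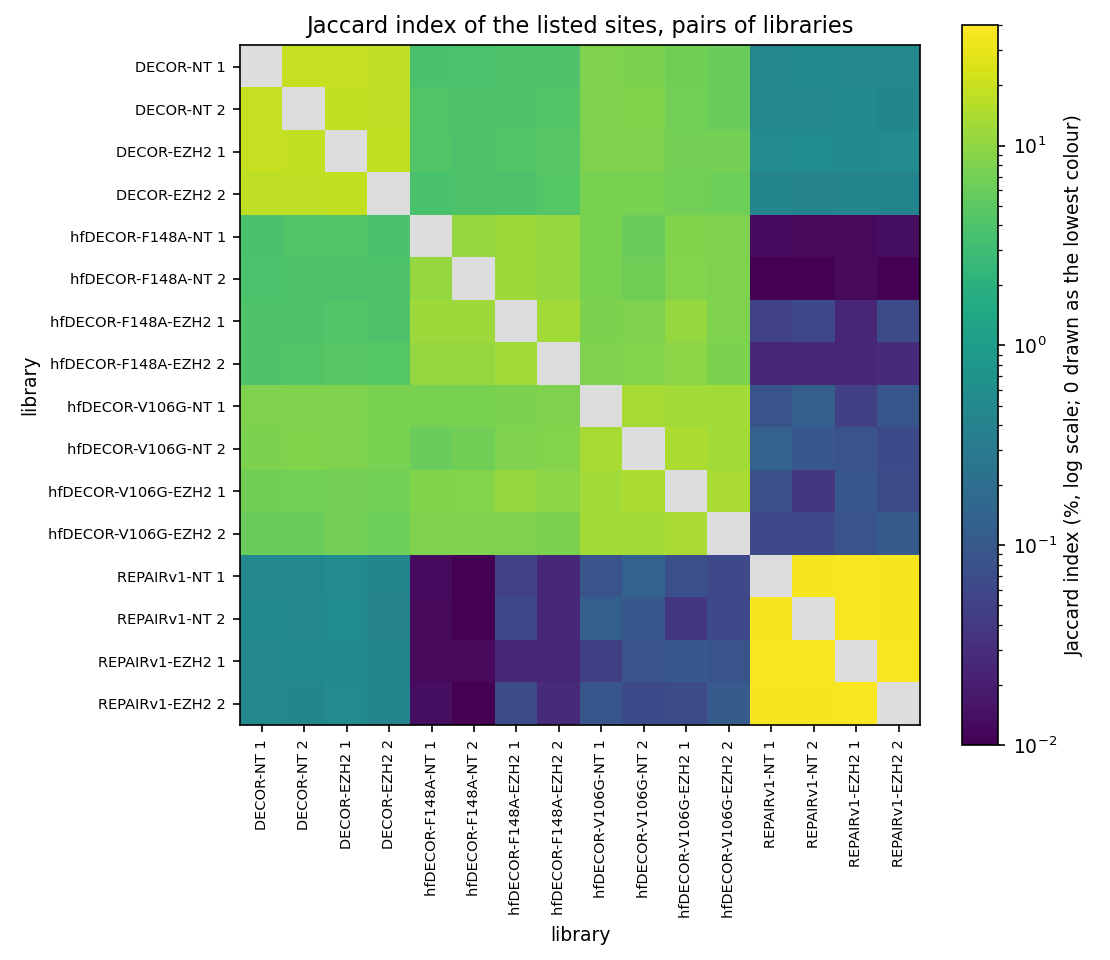
Jaccard index of the listed sites for every pair of the 16 libraries, in percent on a log colour scale, with 0 drawn in the lowest colour and the diagonal left grey. The 3 DECOR-type editors form a block, and their pairs with REPAIRv1 lie at 0.571% or below, against at least 35.7% within REPAIRv1.

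Most sites were seen in few libraries. Of all DECOR sites 69.6% were listed in 1 library only, against 79.5% for hfDECOR-F148A, 75.8% for hfDECOR-V106G and 50.1% for REPAIRv1. All 4 libraries of an editor listed 345 DECOR, 15 hfDECOR-F148A, 38 hfDECOR-V106G and 2426 REPAIRv1 sites. Among these, the DECOR site with the highest level was position 12514526 of chromosome 6, at 74.8% ± 11.3 (SD, n = 4), followed by 135895908 on chromosome 9 at 59.1% ± 3.90. Position 75370025 of chromosome 14 was listed in all 12 libraries of the DECOR-type editors and in 0 REPAIRv1 libraries. Its level was 53.6% ± 12.7 with DECOR, 43.1% ± 3.56 with hfDECOR-V106G and 33.7% ± 2.62 with hfDECOR-F148A. Position 14627532 of chromosome 19 stood at 52.0% ± 3.69 with DECOR and 30.9% ± 4.74 with hfDECOR-V106G. The leading hfDECOR-F148A site was 14626094 on chromosome 19, at 37.0% ± 13.8. The hfDECOR-V106G list also had 207027302 on chromosome 2 at 34.7% ± 3.01 and 133201353 on chromosome 12 at 30.9% ± 4.42, the latter in 2 DECOR libraries. REPAIRv1 was led by 79614895 on chromosome 15 at 80.1% ± 9.77, 48890109 on chromosome 8 at 79.9% ± 10.7 and 156209533 on chromosome 1 at 78.02% ± 5.39. None of the 5 leading REPAIRv1 sites was listed in a library of another editor.

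Some regions took a different share of the sites of DECOR and of REPAIRv1. The region from 14600000 to 14699999 on chromosome 19 held the most sites for all 3 DECOR-type editors, with 27 ± 3.46 sites per DECOR library (SD, n = 4), 14.5 ± 2.52 per hfDECOR-F148A library and 12.75 ± 3.10 per hfDECOR-V106G library. REPAIRv1 libraries listed 3 ± 0.816 there, on lists 2.78 times as long. Its share of all sites was 0.995% for DECOR and 0.0394% for REPAIRv1, a log2 difference of 4.47 (SE 0.28, limma adjusted p = 2.34e-05). The region from 62100000 on chromosome 2 held 11.75 ± 2.87 DECOR sites and 1.75 ± 0.957 REPAIRv1 sites (limma adjusted p = 0.000162). That from 133100000 on chromosome 6 held 5.5 ± 1 and 0.5 ± 0.577 (limma adjusted p = 0.000403). The region from 3600000 on chromosome 2 held 5.5 ± 0.577 DECOR sites and none in REPAIRv1 libraries (limma adjusted p = 4.93e-06). Where an editor listed no site in a region, its values there vary only through the library totals. Its spread is then very small, and the limma p can come out too low.

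In the other direction, the region from 41900000 on chromosome 22 held 8.75 ± 2.50 REPAIRv1 sites and no DECOR site (limma adjusted p = 0.000419), and that from 175700000 on chromosome 5 held 8 ± 0.816 and none (adjusted p = 0.00038). The same limit on p holds for these regions without a DECOR site. The region from 65600000 on chromosome 11 held 10.5 ± 2.38 REPAIRv1 sites and 0.5 ± 1 DECOR sites (adjusted p = 0.0104). By sites in both replicates of a guide condition, REPAIRv1 was led by 2 regions that were not called by share. That from 62300000 on chromosome 11 held 21 ± 2.31 REPAIRv1 and 11.5 ± 1.29 DECOR sites (limma adjusted p = 0.0955), and that from 64800000 on chromosome 11 held 23 ± 1.63 and 8 ± 2.16 (limma adjusted p = 0.965). Some regions held about as many sites for both editors. The region from 3900000 on chromosome 19 held 18.5 ± 5.45 DECOR and 18.25 ± 1.71 REPAIRv1 sites, and that from 99600000 on chromosome 7 held 16.5 sites for each. On lists of unequal length this is a higher share for DECOR, with a log2 difference of 1.44 in both regions (SE 0.30 and 0.31, limma adjusted p = 0.00716 and 0.00796).

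Of 1564 regions tested, limma called 436 between DECOR and REPAIRv1 by share of sites. DECOR had the higher share in 220 and the lower in 216. That split depends on the scaling, with 195 higher and 315 lower at a pseudocount of 0.25, 328 and 79 at a pseudocount of 1, 178 and 369 with a pseudocount scaled to the library total, and 44 and 940 without division by the total. With sites at 20% or more 220 regions were called, and with at least 16 sites summed 265.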

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

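The regions named here were defined after the data were seen, in place of genes. Among 60 groups of 4 libraries of an editor (site counts, median levels, named sites and named regions), 2 had a library far from the other 3, and chance gives about 1 in 20 groups. For hfDECOR-F148A, NT replicate 1 listed 1 site in the region from 3900000 on chromosome 19, against 6 to 7 in the other libraries, a gap of 0.833 of the range. For hfDECOR-V106G, NT replicate 1 listed 3 sites in the region from 4300000 on chromosome 19 and the other libraries 2 each, so the gap is the whole range, a ratio of 1, and amounts to a single site. No guide effect on site count or median level differed between editors after adjustment over 8 exact permutation tests. The lowest unadjusted p was 0.0355 for the site count of hfDECOR-F148A, adjusted p = 0.284, where the log2 change with the EZH2 guide was 0.06 against a mean of -0.18 in the other editors.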

How the results depend on the processing

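The alternatives for regions, the count of further sites near the target, and the alternative that leaves those sites out were chosen after seeing the data. The site counts kept their direction in all 6 pairs of editors under every alternative run (3 pairs at 50% or more), and their calls except under the coarser permutations: with the replicate block the folds stay 2.78, 6.03, 10.99, 16.7, 30.5 and 1.82 (REPAIRv1 over DECOR, DECOR over hfDECOR-V106G, DECOR over hfDECOR-F148A, REPAIRv1 over hfDECOR-V106G, REPAIRv1 over hfDECOR-F148A, hfDECOR-V106G over hfDECOR-F148A) and the exact permutation p is 0.125, and within guide conditions it is 0.0556, each the smallest possible, so these say nothing of stability. The same holds for the median levels, with differences of 8.35, 1.72, 2.80, 10.1, 11.1 and 1.08 points. The labels do not say whether the replicate numbers pair the samples, and no clear pairing was seen (correlations of deviations from -0.0144 to 0.0273 over regions of DECOR and REPAIRv1, and 0.0603, 0.158 and 0.0146 over sites of DECOR, hfDECOR-V106G and REPAIRv1 between the guides). Low correlations over sparse lists cannot exclude a pairing. With the block 323 regions were called in place of 436.

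Levels depended on the site set. Among sites at 20% or more, the differences in median level were 5.53 points for REPAIRv1 over DECOR, 6.13 over hfDECOR-V106G and 5.23 over hfDECOR-F148A (exact permutation p = 0.0286 and adjusted p = 0.0571 each, the call ending through the adjustment), 0.600 for DECOR over hfDECOR-V106G, -0.300 for DECOR over hfDECOR-F148A and -0.900 for hfDECOR-V106G over hfDECOR-F148A. At 50% or more they were 2.93 for REPAIRv1 over DECOR, -7.49 for DECOR over hfDECOR-F148A and -4.56 for REPAIRv1 over hfDECOR-F148A, on few sites, and no value came from hfDECOR-V106G. With sites in both replicates they were 9.49, 1.13, 2.16, 10.6, 11.7 and 1.04, in the order of the 6 pairs above, with adjusted exact permutation p from 0.0571 to 0.314, and 0.0286 unadjusted in the 3 pairs with REPAIRv1. The mean in place of the median gave 0.274 for the hfDECOR versions. At sites listed by both editors, with medians over the sites each library listed, REPAIRv1 over DECOR gave 5.67 and over hfDECOR-V106G 7.06 (adjusted exact permutation p = 0.0429 each), REPAIRv1 over hfDECOR-F148A -2.30 (SE 11.8, on 11 sites) and the hfDECOR versions 0.863. Adjusted p over all these alternatives ran from 0.0286 to 1. Without 1 library, DECOR over hfDECOR-V106G ran from 1.55 (without DECOR-EZH2 replicate 1) to 1.95, and the hfDECOR versions from 0.851 to 1.25, the call ending without hfDECOR-F148A-NT replicate 2, either hfDECOR-F148A-EZH2 replicate, hfDECOR-V106G-NT replicate 2 or hfDECOR-V106G-EZH2 replicate 2. The cause was not tested.

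The guide effect on the median level, uncalled throughout, was 0.0461 points at 20% or more, and without 1 library ran from -0.234 to 0.0636. The excess in Jaccard index for the same guide was 0.277 points with the replicate block (exact permutation p = 0.0625, the smallest possible), 0.858 at 20% or more, 0.199 without the sites near the target, -0.260 as a share of the shorter list, and from -0.0663 to 0.512 without 1 library. Its call ended without DECOR-NT replicate 1 or 2, the second replicate of DECOR-EZH2, hfDECOR-V106G-EZH2, REPAIRv1-NT or REPAIRv1-EZH2, either hfDECOR-F148A-EZH2 replicate, or hfDECOR-V106G-NT replicate 1, with the sign turned without hfDECOR-F148A-EZH2 replicate 2. Its p ran from 0.0123 to 0.617.

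The overlap of DECOR and REPAIRv1 was 0.580% of the smaller set for sites in all libraries, 2.92% for sites in any library, 1.45% at 20% or more, and 1.92% to 2.38% without 1 library. DECOR with hfDECOR-V106G gave 64.5% for any library, 68.4% at 20% or more and 66.3% to 82.4% without 1 library. DECOR with hfDECOR-F148A gave 86.7% for all libraries, 65.1% for any, 69.6% at 20% or more and 63.7% to 80.2% without 1 library. The hfDECOR versions gave 53.3% for all libraries, 32.0% for any and 31.2% to 52.0% without 1 library. REPAIRv1 with hfDECOR-V106G gave 2.63% for all libraries, 2.58% for any and 0.912% (without REPAIRv1-EZH2 replicate 1) to 1.65% without 1 library. REPAIRv1 with hfDECOR-F148A gave 0% for all libraries and 0% to 1.98% without 1 library, 0% without either hfDECOR-F148A-EZH2 replicate, 0.637% without any 1 REPAIRv1 library and 1.98% without hfDECOR-F148A-NT replicate 1. Regions called numbered 265 of 816 tested with at least 16 sites summed and 984 of 1564 without division by the total. They numbered 220 of 1263 at 20% or more and 241 of 917 with windows of 1000 kb. The target position kept its Fisher p of 0.000155 without any 1 library. That value is fixed by its listing in every EZH2 and no NT library, so it says nothing of stability. The mean count of further sites near it, EZH2 minus NT, was 1.38 to 1.88 without 1 library. Of 32 named regions, 29 moved by more than their SD at 20% or more. Guide-dependent sites stayed at 0 calls by limma in every setting run. No coverage minimum or gene assignment could be run without depth or a GRCh37 annotation. The lists hold only A-to-G rates, so no filter on substitution type was run, and 0 sites lay on the mitochondrial chromosome. The guide results had no value at 50% or more, since a library had 0 such sites. Depth limits whether a missing site was unedited or unread.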

Other observations

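The tests of chromosome share, retention by level, listing rates and DECOR sites at 30% or more and the measure of neighbouring sites were chosen after the data were seen. Chromosome 19 took a larger share of the hfDECOR lists than of the others. It held 18.7% ± 1.72 of the hfDECOR-F148A sites (SD, n = 4), 15.5% ± 2.17 for hfDECOR-V106G, 10.9% ± 0.550 for DECOR and 9.18% ± 0.275 for REPAIRv1, while 7.41% of coding genes lie there in GENCODE 29. In each of the 6 pairs every library of one editor lay above every library of the other (exact permutation p = 0.0286, the smallest possible). Chromosome 19 was singled out among 23 because it led. Adjusted over the chromosomes of a pair, its exact permutation p ran from 0.0657 to 0.219, so no pair passed. With a smallest exact permutation p of 0.0286, a single chromosome cannot pass over 23 tests unless many others also reach that p. The adjustment therefore cannot decide whether the share of chromosome 19 differed. The region from 14600000 held 5.86% of all hfDECOR-F148A sites, and without it the share of chromosome 19 was 13.7% ± 1.83, 12.9% ± 1.85, 10.0% ± 0.422 and 9.15% ± 0.283. The libraries of DECOR and hfDECOR-V106G then overlapped, and so did those of the hfDECOR versions. In the exact permutation test over all chromosomes, 0 of 23 passed the adjustment in any pair of editors. Per pair, 3 to 10 had an unadjusted p under 0.05, too few for any to pass.

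How closely the sites lay together could not be compared between editors. Another site within 50 bases was listed for 24.5% of DECOR sites, 22.5% of REPAIRv1 sites, 15.96% of hfDECOR-F148A sites and 13.1% of hfDECOR-V106G sites, on lists of unequal length. Thinning every list to 233 sites removes neighbours from the long lists by itself, so a comparison after thinning says nothing of the editors. DECOR sites of higher level were more often listed by the hfDECOR editors. Of 345 sites in all DECOR libraries, hfDECOR-V106G listed 49.2% of those under 20%, 65.2% of those from 20 to 30% and 72.4% of those at 30% or more. hfDECOR-F148A listed 32.0%, 44.7% and 51.3%, and REPAIRv1 3.12%, 2.84% and 1.32%. The mean DECOR level was 3.79 points higher at sites that hfDECOR-V106G listed (permutation p = 0.0001, adjusted p = 0.0003) and 3.41 points higher for hfDECOR-F148A (permutation p = 0.00058, adjusted p = 0.00087), and for REPAIRv1 the permutation p was 0.47. Sites are not independent replicates. Sites of lower level can also fall below the limit of the hfDECOR lists, so a preference for strong sites cannot be told apart from that limit.

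DECOR and REPAIRv1 had 52 recurrent sites in common. Different transcripts in the lists would leave DECOR sites far from REPAIRv1 sites, but 66.2% of DECOR recurrent sites had a REPAIRv1 site within 500 bases, against 1.07% and 1.21% after shifts of 100 kb. Shifts of 1 to 25 bases gave 1 to 15 shared positions against the 52. A shifted position need not be an adenosine, so these counts cannot tell whether the editors shared more adenosines than an independent choice would give. Random misses between libraries are argued against by the listing rate of DECOR sites in REPAIRv1 libraries, 1.84%, which was 5.83% of the 31.6% in another DECOR library. A different choice of adenosines by the bacterial and the ADAR deaminase may account for this, a hypothesis that was not tested without a GRCh37 sequence, and the authors' filters stay open.

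Most recurrent hfDECOR sites were DECOR sites. Sites edited in these cells whatever the editor would also be listed with REPAIRv1, but the hfDECOR-F148A sites were listed in 0.637% of cases per REPAIRv1 library, 0.990% of the 64.3% per DECOR library. The median ratio to the DECOR level was 0.761 for hfDECOR-F148A and 0.783 for hfDECOR-V106G, between the bounds set beforehand (under 0.5 or at least 0.8), and a site enters only when its level is high enough to be listed. At sites in all libraries of both editors the ratios were 0.650 (13 sites) and 0.682 (28 sites). A small share of DECOR RNA in the hfDECOR libraries, under 0.5, was looked for at the 76 sites in all DECOR libraries at 30% or more. Where listed, their ratio had a lower quartile of 0.549 for hfDECOR-F148A (39 sites) and 0.555 for hfDECOR-V106G (55 sites), and 37 and 21 of the 76 were in no library of these editors. Sites of low ratio can drop out of the lists, so these values cannot decide whether the share was under 0.5. A single share of any size as the only source would give a single ratio. At such sites in all libraries of both editors, ratios ran from 0.292 to 1.02 (8 sites) and from 0.404 to 1.02 (17 sites), a variance of the log ratio 5.79 and 2.96 times that expected from the replicates (permutation of sites within libraries, p = 0.0061 and 0.0053; simulation from the replicate spread, p = 0.0005 and 0.006). DECOR RNA added to editing by the hfDECOR proteins, or in amounts that differ between transcripts, stays open, and so does weaker editing of the same sites.

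hfDECOR-V106G libraries listed 1.36 times as many sites with NT as with EZH2. A few rich regions are argued against as the whole cause, since the ratio was 1.30 without the 10 regions of largest excess, and 1.22 to 1.38 over pairs of libraries. Lower-level sites reached in the NT libraries could not be separated from an equal floor, since the 10th percentiles were 10.8% and 11.5% with NT and 10.9% and 11.3% with EZH2, so that the lowest EZH2 value minus the highest NT value was -0.629 points, within the spread of the replicates. A difference in depth may be a cause and stays open because depth is unknown, and so does the guide itself. This editor's guide effect set against that of the others had an exact permutation p of 0.190, adjusted p = 0.506.

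For the regions called between DECOR and REPAIRv1, other splits of the libraries were tried. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many, the real one with 436 regions, and the highest of the others gave 0. Every other split mixes libraries of both editors, whose lists differ in length and share few sites, so few calls were likely there. The splits therefore cannot exclude chance as the source of the count.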
